A study of Trametes versicolor with 12 samples.

How the data were processed

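Mycelium of the white-rot fungus Trametes versicolor was profiled by RNA sequencing in 12 libraries. Per the labels' protocols, strains BRFM1218 and 1956-1252 were cultured on agar with 4% malt, mycelium was taken after 2 or 4 weeks, total RNA came from 3 separate cultures per strain and age, and libraries followed a standard Illumina protocol. The 4 groups were taken from the strain and age given in the sample labels, with 3 libraries in each.

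The deposited files held 1 row for each of 14296 gene models, named by a protein number. Per the file headers, the authors gave for each gene a count of reads that aligned uniquely, a count of all reads assigned to the gene, and an RPKM value (reads scaled by the length of the model and by library size). The deposited RPKM equalled the count of all reads scaled by a fixed length per gene and by the column total of those counts, and the length implied by it differed between files by at most 1.7e-07 in relative terms. The aligner, the counting tool, the genome build and the use of strand were not given in the sources used here. The files did not pair protein numbers with names. They were matched to the numbers in the locus tags of the RefSeq gene table of the Trametes versicolor v1.0 assembly, which gave a locus tag to 14250 models and a symbol to 42. As a check of this match, the implied model length did not exceed the span of the locus in 100.0% of 13877 matched models, against 60.0% with spans shuffled. The table was used only for names and for which genes are neighbours. It carried no product descriptions, so most of the gene lists written before the data were examined, which were defined by words in descriptions, were not tested here. They were replaced by lists defined by symbol, written after the files were opened and before fold changes were computed: class II peroxidases with their lignin, manganese and versatile peroxidase parts, dye-decolorizing and haem-thiolate peroxidases, laccases and multicopper oxidases with the laccases as a part, and other named haem enzymes.

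The column totals of all reads ranged from 31763162 to 74647672 per library, and 98.7 to 99.17% of them were unique. The level that 3 reads represent lay between 0.0341 and 0.114 in CPM, the read count scaled to library size and normalised as below. Floors and counting intervals cover counting error only. Counts of all reads were analysed with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr left 12648 genes and removed 1648. Libraries were scaled by trimmed means of M values (TMM), a model with 1 mean per group was fitted to all 12 libraries with 8 residual degrees of freedom, and quasi-likelihood tests gave the age effect in each strain, the strain difference at each age, and the interaction (the age effect in 1956-1252 minus that in BRFM1218). Values of p were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and genes with an adjusted p under 0.05 are called. The common biological coefficient of variation was 8.3%. Standard errors of log2 fold changes were computed from the fold change and the F statistic. Levels are TMM-normalised CPM, as mean ± SD over 3 libraries. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 6 lists within a comparison, and again with an estimated correlation. Fry was run beside it. The median of each list was also placed among 10000 random lists matched on expression.

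Named genes followed a rule set before the data were examined. In each age and strain comparison these were the 5 largest rises and the 5 largest falls among called genes with a symbol, a mean of at least 10 CPM over the groups compared and replicates that did not overlap, and 2 members of each list whose test passed. For the interaction they were the 3 largest in each direction, with replicates of the ages not overlapping in at least 1 strain. That reading of overlap was set after a first run without it, which named the same genes. The rule asked for a description, and a symbol was taken in its place. In case descriptions were missing, the rule gave 2 identifiers in each direction. Here 2 without a symbol in each direction were added to the genes with a symbol. Other members of the lists are named as examples and were chosen after their values were seen.

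Fits were tested on simulated counts with the library sizes and dispersions of the real data and 200 genes changed. Unchanged genes had the same mean in all 12 libraries. Far more genes were called in the real data, so the simulations do not test the scaling or the error rates under such broad changes. In the simulated age effect in BRFM1218, on 12576 genes, edgeR called 86% of genes changed 2-fold and 50% of those changed 1.25-fold, with 7 unchanged genes called. In the simulated interaction, on 12574 genes, it called 90% of genes changed 2-fold and 24% of those changed 1.25-fold. Alternatives planned before the data were examined were other size factors (RLE and upper quartile), no filter, a filter at 10 CPM in 3 libraries, DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, a 2-fold minimum, strain differences only on genes with 10 counts in each strain, and leaving out each library. Alternatives added after seeing the data were unique reads, scaling by library size only, and removal of a trend with model length or with expression level. Pairs of replicates had a chi-square per degree of freedom of 5.11 to 33.3 over genes, so none agreed within sampling noise and all 12 libraries were kept. Other computations used Python 3 with numpy and pandas.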

Results

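Gene expression was measured by RNA sequencing in mycelium of Trametes versicolor, a basidiomycete that causes white rot of wood. Strains BRFM1218 and 1956-1252 were each sampled after 2 and 4 weeks of growth on malt agar, with 3 libraries from separate cultures in each of the 4 groups. Reads assigned to genes numbered 31763162, 37237978 and 38609061 in BRFM1218 at 2 weeks, 60610826, 63512650 and 34004441 in BRFM1218 at 4 weeks, 68308352, 74647672 and 60086647 in 1956-1252 at 2 weeks, and 54717436, 59044703 and 59387307 in 1956-1252 at 4 weeks. The first principal component, with 87.1% of the variance, separated the strains, and the second, with 6.0%, separated the ages of BRFM1218. In BRFM1218, 1561 to 1971 gene models had no reads in a library, and in 1956-1252, 1123 to 1205. The comparisons asked how expression changed with culture age in each strain, how the strains differed at each age, and whether the age change differed between strains.

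In BRFM1218, TvLac6, TvLac2, TvLac4 and DyP1 fell between 2 and 4 weeks, and HTP3 and HTP2 rose. TvLac6, encoding a laccase, a copper oxidase of phenols, fell from 92.0 ± 3.97 to 4.98 ± 1.43 CPM (n = 3 per group here and below), a log2 fold change of -4.20 (SE 0.15). TvLac2 fell from 47.0 ± 0.758 to 10.7 ± 1.86 CPM (log2 fold change -2.12, SE 0.12), and TvLac4 from 17.1 ± 1.49 to 4.24 ± 0.444 CPM (-2.01, SE 0.16). DyP1, a dye-decolorizing peroxidase gene and the most abundant transcript among the 42 genes with a symbol, fell from 2114 ± 20.8 to 764 ± 66.6 CPM (-1.47, SE 0.05). HTP3 rose from 7.68 ± 1.38 to 54.6 ± 0.527 CPM (2.82, SE 0.10), and HTP2 from 17.9 ± 2.54 to 74.7 ± 2.10 CPM (2.06, SE 0.09).

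Of 12648 tested genes, 4175 were higher and 3468 lower at 4 weeks in BRFM1218 at an adjusted p under 0.05 in edgeR's quasi-likelihood test, of which 1196 and 746 changed at least 2-fold. Of called genes 54.6% were higher with TMM (trimmed means of M values), 56.0% with library size only and 49.2% with a length trend removed. Trend removal also recentres each library, which by construction draws this share toward an even split. The adjusted p was 4.01e-13 for TvLac6, 1.62e-10 for TvLac2, 6.75e-09 for TvLac4, 2.93e-13 for DyP1, 1.9e-13 for HTP3 and 7.87e-12 for HTP2. LDO2, named for a linoleate diol synthase-type haem enzyme, rose from 51.5 ± 1.79 to 127 ± 4.17 CPM (1.30, SE 0.04), and CCP1, a cytochrome c peroxidase gene, fell from 329 ± 8.56 to 161 ± 8.95 CPM (-1.03, SE 0.05). TvLac3 rose from 14.4 ± 1.83 to 18.2 ± 1.94 CPM (0.34, SE 0.11, adjusted p = 0.0118). This call for TvLac3 ended without BRFM1218 2-week replicate 2 (log2 fold change 0.24, adjusted p = 0.0734), without BRFM1218 4-week replicate 2 (0.24, adjusted p = 0.0653), and when only the BRFM1218 libraries were fitted (0.29, adjusted p = 0.0723). Among genes without a symbol, TRAVEDRAFT_75646 rose from 2.76 ± 0.843 to 183 ± 2.59 CPM and TRAVEDRAFT_153876 from 7.38 ± 1.49 to 314 ± 18.6 CPM. TRAVEDRAFT_103761 fell from 192 ± 6.08 to 4.42 ± 0.593 CPM and TRAVEDRAFT_52566 from 23.2 ± 3.52 to 1.24 ± 0.665 CPM.

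Of 10 lignin peroxidase genes, whose products oxidise non-phenolic lignin units, 8 were higher with age in BRFM1218, 0 were lower and 2 did not pass, and 9 were higher when adjusted over the list alone. The camera test of the list gave an adjusted p of 0.0205, and adjusted p = 0.472 with an estimated correlation. The list median was 1.04 on the log2 scale, at the 99.61 percentile of matched random lists, whose median was 0.26. LiP9 rose from 0.706 ± 0.0888 to 3.07 ± 0.670 CPM (2.13, SE 0.29, adjusted p = 6.26e-06) and LiP4 from 1.15 ± 0.362 to 3.15 ± 0.488 CPM (1.45, SE 0.23, adjusted p = 3.84e-05). Of all 26 class II peroxidases, 13 were higher and 4 lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.127). Of 13 manganese peroxidases, 4 were higher and 2 lower (the same counts adjusted over the list alone; camera adjusted p = 0.418). Of 3 versatile peroxidases, 1 was higher and 2 lower, with a list median of -0.26 and a mean of 0.31. Of 5 dye-decolorizing and haem-thiolate peroxidases, 3 were higher and 1 lower (camera adjusted p = 0.21), and of 8 laccases and multicopper oxidases, 2 were higher and 5 lower (camera adjusted p = 0.153). For the 7 laccases alone these counts were 2 and 4 (camera adjusted p = 0.184), of which the call for TvLac5 was lost in 8 of 23 alternatives. Among manganese peroxidases, the calls for MnP1s, MnP5s and MnP10s were lost in 4 of 23, 2 of 22 and 1 of 23. Of 3 other named haem enzymes, 1 was higher and 2 lower.

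**Figure D1:**
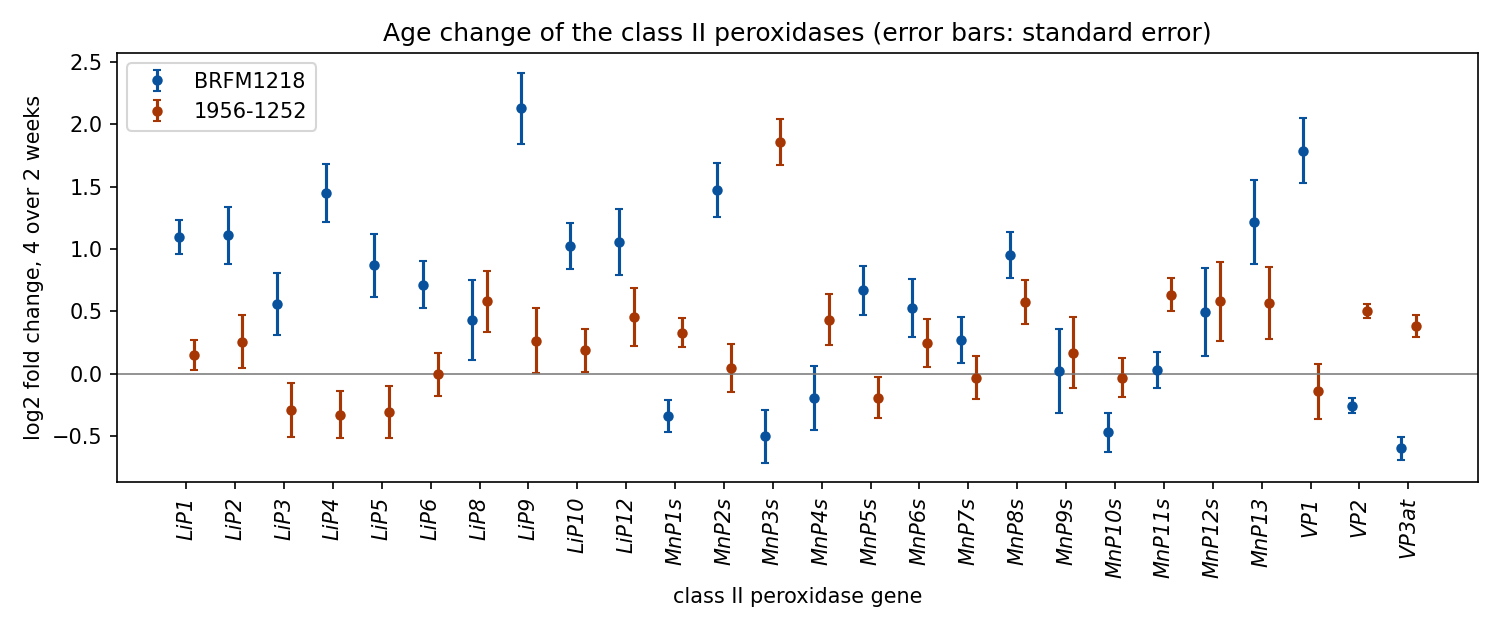
Log2 fold change from 2 to 4 weeks (y axis) of each of 26 class II peroxidase genes (x axis) in BRFM1218 (blue) and 1956-1252 (brown). Points are estimates from 3 libraries per group and bars are standard errors; LiP9 stood at 2.13 in BRFM1218 and 0.26 in 1956-1252, and MnP3s at 1.86 in 1956-1252.

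In 1956-1252, DyP2, HTP1, HTP3, DyP1 and MnP3s rose with age. DyP2 rose from 17.9 ± 0.951 to 134 ± 3.60 CPM (log2 fold change 2.91, SE 0.10), HTP1 from 95.9 ± 1.17 to 239 ± 0.770 CPM (1.32, SE 0.06) and HTP3 from 23.5 ± 1.04 to 62.3 ± 2.44 CPM (1.41, SE 0.08). DyP1 rose from 30.8 ± 1.08 to 69.8 ± 1.38 CPM (1.18, SE 0.05). MnP3s, a gene named as a manganese peroxidase, an enzyme that oxidises manganese(II), rose from 4.72 ± 0.80 to 17.1 ± 0.928 CPM (1.86, SE 0.18).

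In this strain 3176 genes were higher and 2965 lower at 4 weeks, of which 646 and 113 changed at least 2-fold. Of called genes 51.7% were higher with TMM, 59.6% with library size only and 46.6% with a length trend removed, which also recentres each library. The adjusted p was 2.57e-13 for DyP2, 9.07e-12 for HTP1, 4.09e-10 for HTP3, 1.69e-11 for DyP1 and 2.6e-07 for MnP3s. No gene with a symbol met the rule for a fall. Among genes without a symbol, TRAVEDRAFT_137860 rose from 1.39 ± 0.231 to 53.3 ± 5.28 CPM and TRAVEDRAFT_39657 from 16.9 ± 1.63 to 332 ± 12.6 CPM, while TRAVEDRAFT_45814 fell from 27.1 ± 5.95 to 3.69 ± 0.676 CPM and TRAVEDRAFT_153507 from 181 ± 13.1 to 25.4 ± 0.757 CPM.

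All 5 dye-decolorizing and haem-thiolate peroxidases were higher at 4 weeks in 1956-1252, with a list median of 1.32 (5 adjusted over the list alone). The camera test gave an adjusted p of 8.26e-05, and adjusted p = 0.0629 with an estimated correlation. Of 8 laccases and multicopper oxidases, 6 were higher and 0 lower, and of the 7 laccases alone 5 were higher and 0 lower, with the same counts adjusted over the list alone. Each of these lists had a camera adjusted p of 0.0142, and adjusted p = 0.263 with an estimated correlation. TvLac7 rose from 2.88 ± 0.660 to 7.77 ± 0.717 CPM (1.43, SE 0.20, adjusted p = 1.81e-05) and TvLac6 from 5.43 ± 0.752 to 9.37 ± 0.533 CPM (0.78, SE 0.14, adjusted p = 0.000199). Of the 10 lignin peroxidases, 0 were called by edgeR and 0 by DESeq2, 1 was higher at an unadjusted p under 0.05 in edgeR, and the list median was 0.17 (camera adjusted p = 0.759). Of 13 manganese peroxidases, 4 were higher and 0 lower, and of 26 class II peroxidases, 6 and 0, each with a camera adjusted p of 0.125. The calls for MnP1s, MnP8s and TvFet3A were lost in 5 of 23, 1 of 22 and 2 of 23 alternatives. Of 3 versatile peroxidases 2 were higher, and of 3 other named haem enzymes 2 were higher.

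The age change itself differed between the strains in many genes, with TvLac6, TvLac2 and DyP1 moving in opposite directions. The interaction (the age change in 1956-1252 minus that in BRFM1218) was 4.98 on the log2 scale for TvLac6 (SE 0.21), 2.71 for TvLac2 (SE 0.18) and 2.65 for DyP1 (SE 0.08). All 3 fell with age in BRFM1218 and rose in 1956-1252, where TvLac2 went from 4.52 ± 0.285 to 6.80 ± 0.880 CPM. HTP3, HTP2 and LiP1 had the largest interactions in the other direction among genes with a symbol whose mean over the groups was at least 10 CPM, at -1.42 (SE 0.13), -1.09 (SE 0.13) and -0.94 (SE 0.18). HTP2 and HTP3 rose in both strains, by more in BRFM1218.

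The interaction passed in 3241 genes in the direction of 1956-1252 and in 3446 in the other, of which 1125 and 1050 differed at least 2-fold. Of called genes 48.5% were in the direction of 1956-1252 with TMM, 51.5% with library size only and 50.1% with a length trend removed, which also recentres each library. The adjusted p was 3.3e-12 for TvLac6, 1.02e-09 for TvLac2, 3e-14 for DyP1, 5.54e-08 for HTP3, 2.25e-06 for HTP2 and 0.000276 for LiP1. Across genes, which are not independent replicates, the age changes of the strains had a Pearson r of 0.09 and a Spearman rho of 0.14. In all, 4278 genes were called with age in both strains. Of these, 1389 were higher in both (1048 for independent lists), 1199 were lower in both (813 for independent lists), 918 rose in BRFM1218 and fell in 1956-1252 (979), and 772 fell in BRFM1218 and rose in 1956-1252 (871). The 1690 genes with opposite changes all passed the interaction test, which their choice by called changes of opposite sign all but ensures.

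Of the 10 lignin peroxidases, 8 had a lower age change in 1956-1252 than in BRFM1218 and 0 a higher one, with a list median of -0.85 (camera adjusted p = 0.0197, and adjusted p = 0.367 with an estimated correlation). Of the 8 calls, those for LiP3, LiP2 and LiP6 were lost in 9, 6 and 5 of 21 alternatives. Of 8 laccases and multicopper oxidases, 5 had a higher age change in 1956-1252 and 0 a lower one, and of the 7 laccases alone 4 and 0, of which the call for TvLac3 was lost in 4 of 22 alternatives. Their list medians were 0.90 and 0.54, each with a camera adjusted p of 0.0163, and adjusted p = 0.337 with an estimated correlation. These medians lay at the 99.42 and 93.24 percentiles of matched random lists, and that of the lignin peroxidases at 0.58. Adjusted over the list alone the counts were 8 for lignin peroxidases, 6 for laccases and multicopper oxidases and 5 for laccases. Of 26 class II peroxidases, 5 were higher and 11 lower (camera adjusted p = 0.387), of 13 manganese peroxidases 3 and 2 (camera adjusted p = 0.843), of 3 versatile peroxidases 2 and 1 (median 0.76, mean -0.06), of 5 dye-decolorizing and haem-thiolate peroxidases 3 and 2 (camera adjusted p = 0.387), and of 3 other named haem enzymes 2 and 1. TRAVEDRAFT_103761 had an interaction of 8.45 (SE 0.25), rising from 0.223 ± 0.124 to 1.88 ± 0.280 CPM in 1956-1252. TRAVEDRAFT_74496 had -5.86 (SE 0.19), rising from 1.70 ± 0.260 to 15.6 ± 2.07 CPM in BRFM1218 and falling from 35.2 ± 0.520 to 5.57 ± 0.626 CPM in 1956-1252. TRAVEDRAFT_153876 had -5.58 (SE 0.15), at 10.2 ± 0.924 and 9.08 ± 0.846 CPM in 1956-1252. The fitted interaction of TRAVEDRAFT_137860 was 7.86 (SE 2.77, adjusted p = 0.027). It rested on 1 read over the 6 BRFM1218 libraries, and the call ended without BRFM1218 2-week replicate 1 and with unique reads.

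**Figure D2:**
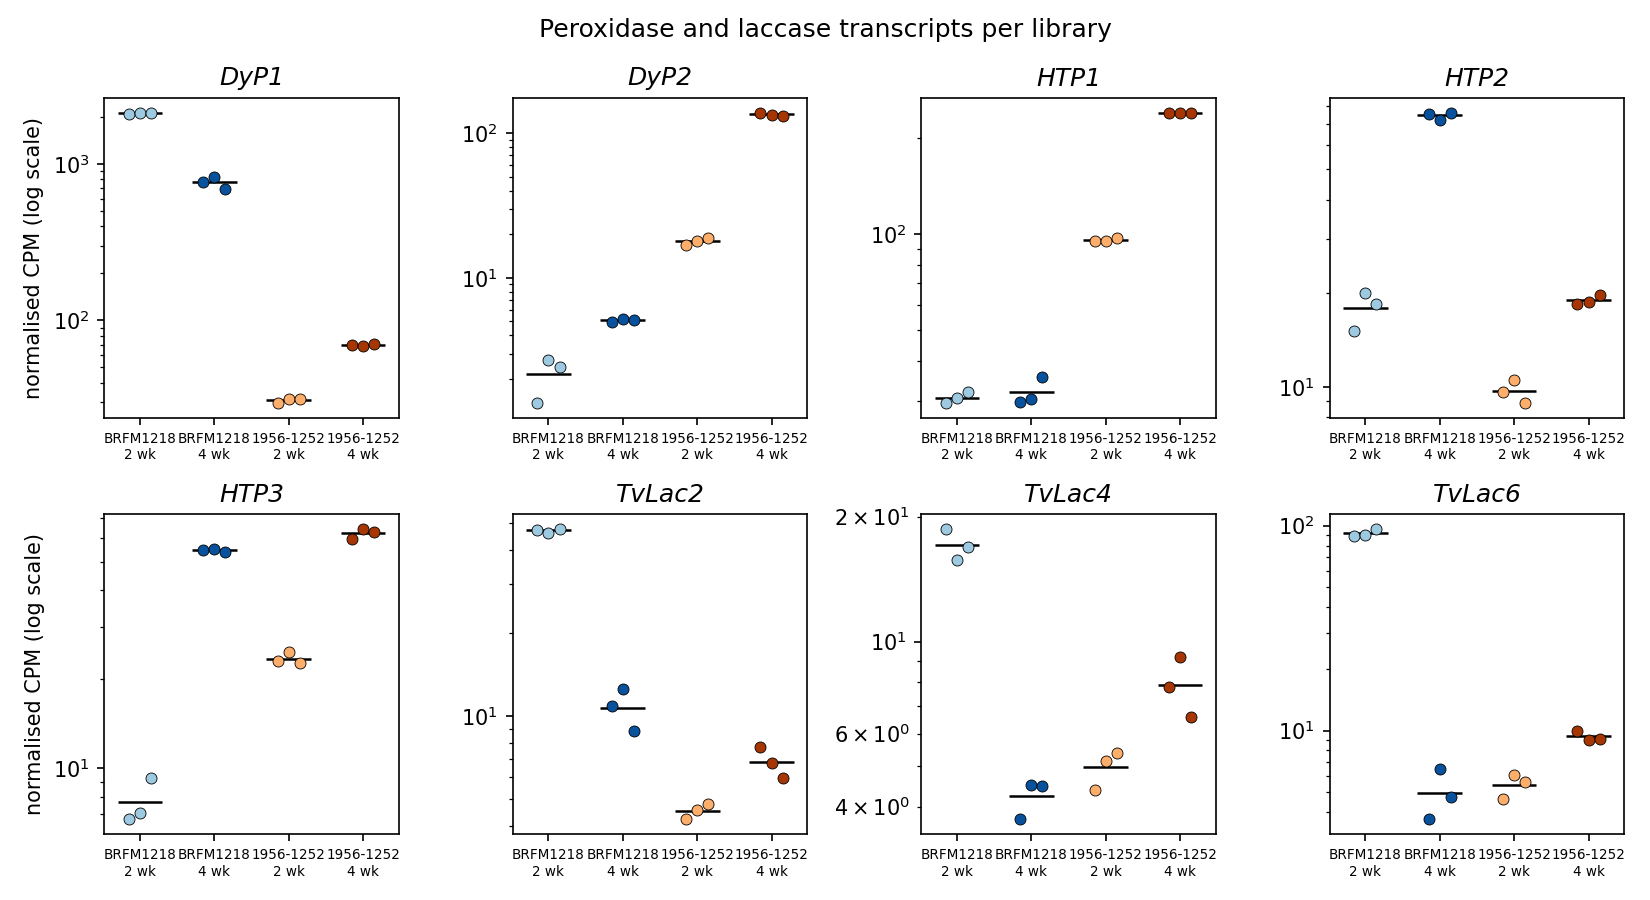
Normalised CPM (y axis, log scale) of 8 peroxidase and laccase genes in each of 12 libraries, by strain and age (x axis). Points are libraries and lines are means of 3; TvLac6 went from 92.0 to 4.98 CPM in BRFM1218 and from 5.43 to 9.37 CPM in 1956-1252.

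**Figure D3:**
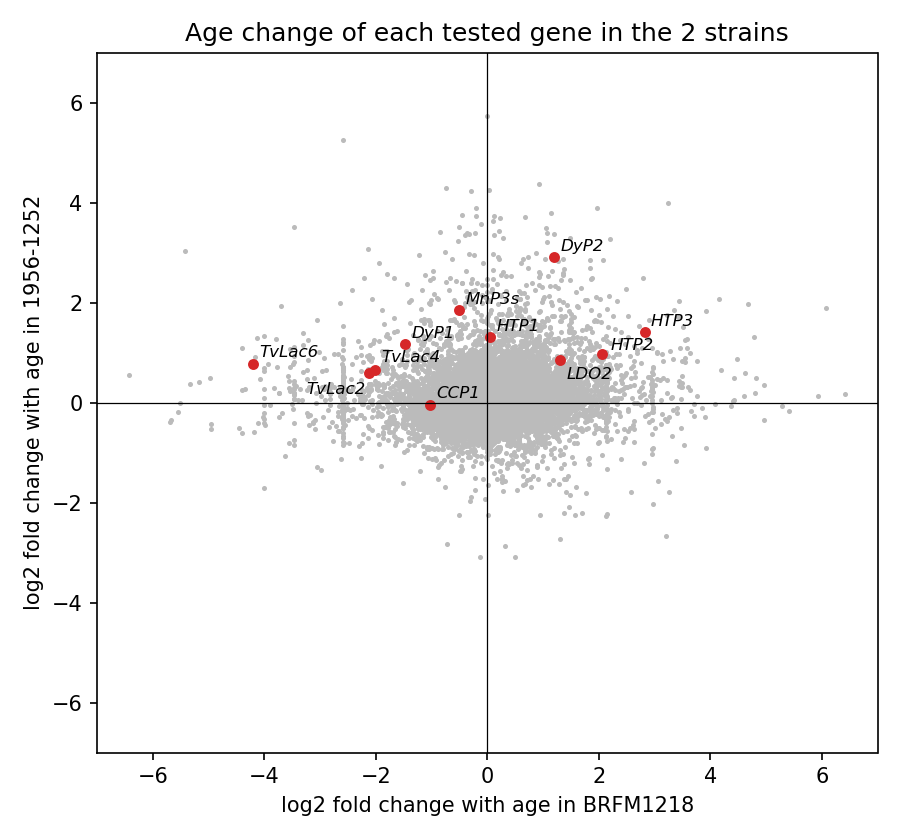
Log2 fold change from 2 to 4 weeks in BRFM1218 (x axis) and in 1956-1252 (y axis) for each tested gene, with 11 genes with a symbol in red. Pearson r across genes was 0.09; 1 gene lies outside the plotted range, and TvLac6, TvLac2, TvLac4 and DyP1 lie left of 0 and above 0. The vertical lines of points are made of genes with few reads in BRFM1218, where 226 tested genes had 1 to 3 reads over the 6 libraries and 147 had 0. Over the 11431 genes with at least 100 reads there, a limit chosen after the figure was drawn, Pearson r was 0.11.

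At 2 weeks, DyP1 and several laccases were far lower in 1956-1252 than in BRFM1218, and DyP2 and LDO2 were higher. DyP1 was at 30.8 ± 1.08 CPM against 2114 ± 20.8 in BRFM1218, a log2 difference of -6.10 (SE 0.06). TvLac6 was at 5.43 ± 0.752 against 92.0 ± 3.97 CPM (-4.08, SE 0.15) and TvLac2 at 4.52 ± 0.285 against 47.0 ± 0.758 CPM (-3.38, SE 0.13). DyP2 was at 17.9 ± 0.951 against 2.17 ± 0.710 CPM (3.02, SE 0.13) and LDO2 at 325 ± 6.19 against 51.5 ± 1.79 CPM (2.66, SE 0.04).

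At this age 5614 genes were higher and 5105 lower in 1956-1252, of which 3687 and 2946 differed at least 2-fold. The strain values at both ages, and the bounds for single genes, assume that reads of both strains aligned equally well, which was not tested here. The reference strain of the alignment was not given in the sources used here. The adjusted p was 4.48e-21 for DyP1, 2.86e-14 for TvLac6, 6.81e-14 for TvLac2, 3.91e-13 for DyP2 and 8.34e-19 for LDO2. CCP1 (-2.74, SE 0.05) and VP2, a versatile peroxidase gene (-2.02, SE 0.06), were also lower in 1956-1252, and HTP1 (1.64, SE 0.06), HTP3 (1.61, SE 0.10) and LiP1 (1.41, SE 0.13) were higher. The split depended on the scaling: 52.4% of called genes were higher in 1956-1252 with TMM, 52.9% with RLE, 61.9% with upper quartile factors and 67.9% with library size only. In the same order, the median log2 difference of all tested genes was 0.09, 0.11, 0.39 and 0.60. TRAVEDRAFT_53587 and TRAVEDRAFT_23834 had 0 reads in BRFM1218 at 2 weeks and were at 858 ± 29.0 and 392 ± 19.2 CPM in 1956-1252, at least 25400-fold and at least 11600-fold higher against a floor of 3 reads over the group. TRAVEDRAFT_52808 was at 187 ± 1.34 CPM in BRFM1218 with 1 read in 1956-1252 (ratio 44800, 95% counting interval 8040 to 1770000). TRAVEDRAFT_52413 was at 62.7 ± 2.77 CPM in BRFM1218 with 3 reads in 1956-1252 (ratio 5030, 95% counting interval 1720 to 24400).

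No list passed the camera test at 2 weeks. Of 10 lignin peroxidases, 8 were higher in 1956-1252 and 0 lower, and of 13 manganese peroxidases 7 and 1, with camera adjusted p of 0.13 and 0.198. Their list medians of 1.05 and 0.52 lay at the 68.77 and 43.63 percentiles of matched random lists, whose medians were 0.68 and 0.62. Neither list thus stood apart from genes of like expression. Of 26 class II peroxidases, 16 were higher and 3 lower (camera adjusted p = 0.13, list median 0.81 at the 71.18 percentile). The calls for LiP10, LiP12, MnP13 and MnP3s among these were lost when a trend with expression level was removed. Their estimates had the other sign (adjusted p = 0.906, 0.567, 0.334 and 0.512 in edgeR). That for VP3at, lower by TMM, was lost with library size only, with an estimate of the other sign (adjusted p = 0.0831). The calls for MnP3s and MnP13 were lost with the sign unchanged in a further 8 of 24 and 5 of 23 alternatives. Of 8 laccases and multicopper oxidases, 1 was higher and 5 lower (camera adjusted p = 0.198). Of the 7 laccases alone these counts were 1 and 4 (camera adjusted p = 0.198). The calls for TvFet3A, TvLac1 and TvLac7, the higher one, were lost in 3 of 24, 3 of 23 and 1 of 23 alternatives. Of 5 dye-decolorizing and haem-thiolate peroxidases, 3 were higher and 2 lower (camera adjusted p = 0.67), and the list median of 1.61 and mean of -0.14 differed in sign, with camera pointing up and fry down. Of 3 versatile peroxidases, 1 was higher and 2 lower, and of 3 other named haem enzymes, 1 was higher and 2 lower. All counts at 2 weeks were the same adjusted over the list alone.

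At 4 weeks DyP2 and HTP1 were higher in 1956-1252, and DyP1 and HTP2 lower. DyP2 was at 134 ± 3.60 CPM against 5.09 ± 0.10 in BRFM1218 (4.72, SE 0.11), and HTP1 at 239 ± 0.770 against 32.0 ± 3.24 CPM (2.91, SE 0.06). DyP1 was at 69.8 ± 1.38 against 764 ± 66.6 CPM (-3.45, SE 0.06), and HTP2 at 19.0 ± 0.661 against 74.7 ± 2.10 CPM (-1.97, SE 0.09). TvLac6, 92.0 CPM in BRFM1218 at 2 weeks, was at 4.98 ± 1.43 CPM in BRFM1218 and 9.37 ± 0.533 CPM in 1956-1252 at 4 weeks (0.90, SE 0.15).

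At this age 5684 genes were higher and 5131 lower in 1956-1252, of which 3553 and 2911 differed at least 2-fold. The adjusted p was 8.37e-17 for DyP2, 2.39e-17 for HTP1, 7.49e-19 for DyP1 and 1.02e-12 for HTP2. LDO2 (2.21, SE 0.04), MnP1s (1.58, SE 0.12) and VP3at (0.64, SE 0.09) were also higher, and CCP1 (-1.74, SE 0.05), VP2 (-1.26, SE 0.06) and MnP10s (-0.89, SE 0.16) were lower. Of called genes 52.6% were higher in 1956-1252 with TMM, 53.2% with RLE, 61.8% with upper quartile factors and 68.8% with library size only. In the same order, the median log2 difference of all tested genes was 0.11, 0.13, 0.40 and 0.66. TRAVEDRAFT_17336 and TRAVEDRAFT_53588 had 0 reads in BRFM1218 and were at 332 ± 16.8 and 223 ± 4.93 CPM in 1956-1252, at least 14600-fold and at least 9800-fold higher. TRAVEDRAFT_52808 and TRAVEDRAFT_42523 had 0 reads in 1956-1252 and were at 177 ± 10.7 and 29.1 ± 1.79 CPM in BRFM1218, at least 12500-fold and at least 2040-fold lower in 1956-1252.

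No list passed the camera test at 4 weeks. Of 10 lignin peroxidases, 4 were higher in 1956-1252 and 2 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.722), and of 26 class II peroxidases 11 and 5 (10 and 3 adjusted over the list alone; camera adjusted p = 0.603). Of 13 manganese peroxidases, 6 were higher and 2 lower (camera adjusted p = 0.603). The medians of the lignin, class II and manganese peroxidases lay at the 24.16, 23.23 and 51.9 percentiles of matched random lists. Of 8 laccases and multicopper oxidases, 6 were higher and 2 lower, and of the 7 laccases alone 5 and 2 (camera adjusted p = 0.603 for each). The calls for LiP2, LiP4 and TvLac1 were kept in 10, 10 and 11 of 23 alternatives and that for TvLac5 in 10 of 24. With library size only the lower calls for LiP2, MnP8s and TvLac1 were lost, with estimates of the other sign (adjusted p = 0.763, 0.456 and 0.83 in edgeR). The higher calls for LiP4 and MnP5s were lost likewise when a trend with expression level was removed (adjusted p = 0.0981 and 0.738). Of 5 dye-decolorizing and haem-thiolate peroxidases, 3 were higher and 2 lower (median 0.19, camera up with adjusted p = 0.899, fry down). The higher call for HTP3, whose value is that median, was lost in 5 of 24 alternatives. Of 3 versatile peroxidases, 1 was higher and 1 lower, and of 3 other named haem enzymes 2 and 1. Strain differences at the 2 ages were shared in 4714 genes higher in 1956-1252 (2523 for independent lists) and 4239 genes lower (2071 for independent lists), and their Pearson r across genes was 0.92.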

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

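The tests of shared reads, of absent or diverged segments and of background reads were chosen after related values had been seen. So was the test of floor genes at 2 to 5 CPM, with the reading of intervals against 0.3. Removal of a length trend was an alternative added after seeing the data. The other tests in this part were chosen before. The first results here are those whose age change differed between the strains by the interaction test of edgeR, given as the age change in 1956-1252 minus that in BRFM1218 on the log2 scale. There were 3241 genes with a higher and 3446 with a lower age change in 1956-1252. Of 100 splits of the age labels within strains, drawn from 200, only the real split gave as many genes as the real 6687. The highest other gave 3784. The other splits drawn mix the ages in at least 1 strain, which lowers their counts whether or not the age changes differ. The split that exchanges the ages in 1 strain measures the sum of both age changes. It was not among those drawn and called 7443 genes, more than the real split. These splits therefore cannot decide whether the interaction count arose by chance. For the other comparisons the 6 libraries make only 10 splits, too few for a share under 0.05. The real counts were 7643 genes for age in BRFM1218, 6141 for age in 1956-1252, 10719 for strain at 2 weeks and 10815 for strain at 4 weeks, and no other split called a gene in edgeR, with up to 815, 482, 85 and 103 genes at an unadjusted p under 0.05. DESeq2 was not run on these splits.

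The lists that passed the camera test had medians of -0.85 for the lignin peroxidases, 0.90 for laccases and multicopper oxidases, and 0.54 for laccases. All 3 calls were lost with an estimated correlation, at adjusted p of 0.367, 0.337 and 0.337. The named genes with a higher age change in 1956-1252 were TvLac6 (4.98), TvLac2 (2.71), TvLac4 (2.67), DyP1 (2.65), MnP3s (2.36), DyP2 (1.70), HTP1 (1.27), TvFet3A (1.26), LDO1 (1.23), CCP1 (1.0), VP3at (0.98), VP2 (0.76), MnP1s (0.67) and TvLac3 (0.43), whose call was kept in 18 and lost in 4 of 22 alternatives. Those with a lower one were LiP9 (-1.86), LiP4 (-1.78), HTP3 (-1.42), HTP2 (-1.09), LiP1 (-0.94) and LDO2 (-0.45). The named genes include those with opposite changes given below, which all had a higher one. Other genes with a symbol also passed. With a lower age change these were VP1 (-1.93), MnP2s (-1.43), LiP5 (-1.18), MnP5s (-0.86), LiP2 (-0.85), LiP3 (-0.85), LiP10 (-0.84) and LiP6 (-0.72). With a higher one it was MnP11s (0.60). Among genes without a symbol the values were 8.45 for TRAVEDRAFT_103761, 7.86 for TRAVEDRAFT_137860, 5.08 for TRAVEDRAFT_52566, 5.03 for TRAVEDRAFT_39657, -5.86 for TRAVEDRAFT_74496, -5.58 for TRAVEDRAFT_153876, -4.17 for TRAVEDRAFT_75646, -3.19 for TRAVEDRAFT_45814 and -2.11 for TRAVEDRAFT_153507.

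DyP1, LDO1, MnP1s, TvFet3A, TvLac2, TvLac4, TvLac6, VP2 and VP3at, 9 of the 42 genes with a symbol, fell with age in BRFM1218 and rose in 1956-1252. With a gene length trend removed, 8 of the 9 kept both calls and opposite signs. Among the 8, the fall of LDO1 in BRFM1218 shrank from -0.37 (SE 0.04) to -0.13 (SE 0.05, adjusted p = 0.0288). The rise of MnP1s in 1956-1252 went from 0.33 (SE 0.12, adjusted p = 0.0264) to 0.25 (SE 0.11, adjusted p = 0.0767), a smaller estimate with a similar error, which ended its call, while its fall in BRFM1218 went from -0.34 (SE 0.13) to -0.52 (SE 0.12, adjusted p = 0.00155). With unique reads, a test of reads shared between paralogs, 9 did. Against a single library as the source, at least 7 did so whichever library was left out, the lowest being without 1956-1252 2-week replicate 2, where MnP1s and TvFet3A lost a call. MnP1s also lost a call without BRFM1218 2-week replicate 1 or 3, BRFM1218 4-week replicate 1 or 3, 1956-1252 2-week replicate 3 and 1956-1252 4-week replicate 2 or 3, and TvFet3A, with 86.47% unique reads, without 1956-1252 2-week replicate 1. The values argue against each of these as the whole source of the pattern, and a length trend stays open as part of the fall of LDO1. The age change of all 9 differed between the strains by the interaction test. Choosing genes called in opposite directions all but ensures this, so it adds no further evidence. The pattern was found and tested on the same data, and the source of this difference stays open.

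In BRFM1218, 122 genes had at most 3 reads over 6 libraries while reaching at least 5 CPM in 1956-1252, against 9 genes the other way. CPM here was scaled by library total without TMM, so in normalised CPM the limit was lower in 1956-1252 than in BRFM1218. Lower depth of the BRFM1218 libraries is argued against, since thinning every library to the smallest total left 137 genes against 14, and so are reads shared between near-identical genes, since the median share of unique reads of these genes was 100%. Of the 122 genes, 26.2% were next to another of them, against a mean of 1.88% in random draws, in runs such as 5 genes from TRAVEDRAFT_43397 to TRAVEDRAFT_43400. Segments absent from BRFM1218 or too diverged to align may account for this, but of 464 genes at least 16-fold lower in BRFM1218 that still had reads there 93 were neighbours of each other, so the test, which asked for more than 2 times that share, left it open. Subsets of those genes of the same size, a comparison added after that result, had a mean of 5.35% and a highest value of 18%, and clusters of genes that are silent in BRFM1218 stay open as well.

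Genes of low abundance were higher in 1956-1252, with a median log2 difference of 1.10 at 2 weeks among 636 genes at 1 to 2 CPM, against -0.42 in genes over 100 CPM. These CPM limits apply to means over all libraries, scaled by library total without TMM. By deposited RPKM, background reads spread over all genes in 1956-1252 would have to add 1.45 RPKM at the genes of 1 to 2 CPM. Such a background would leave few models far below that. RPKM was scaled by library total and the log2 differences by TMM, so 1.45 also holds the difference in scaling. A background matched to the TMM difference would be smaller and was not computed. A first test, the 20th percentile in 1956-1252 of models of at least 1 kb, lay at 4.54 RPKM, compatible with a background. It was dropped because most models are expressed, so it could not come out against a background. Of 8169 models of at least 1 kb with over 10 reads in 1956-1252, 3.91% lay under 0.723 RPKM, between the bounds of 1 and 5% set for that test, and of all 8546 models of at least 1 kb 8.14% did. Of these models, 227 were at or under 0.2 RPKM in BRFM1218 with over 10 reads in each strain. Of the 227, 47.1% (95% interval over models 40.5 to 53.9%) lay under 0.723 RPKM in 1956-1252. That argues against an even background of 1.45 RPKM as the whole source. A smaller one was not tested. This last test was chosen after the results of the others were seen. Background confined to some genes was not tested. Genes below the floor in BRFM1218 are argued against as the whole source, which would bring the median under 0.3. Without genes at 10 or fewer reads there it was 0.67 (bootstrap interval over genes 0.47 to 1.03) at 1 to 2 CPM and 0.78 (0.67 to 0.91) in 1275 genes at 2 to 5 CPM. The first bootstrap interval reached below the bound of 0.6 set beforehand, and genes below the floor stay open as part of the source. The intervals over genes and over models treat these as independent and hold no spread between cultures. A biological difference between the strains stays open and untested.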

How the results depend on the processing

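The alternatives with unique reads, library size only and a trend removed were added after seeing the data, and the others were planned before. Counts of called genes stayed within 1.5 times their value in 232 of 242 comparisons with an alternative. The other 10 came from the 2-fold minimum, which by construction keeps fewer genes: 1196 higher and 746 lower with age in BRFM1218, 646 and 113 with age in 1956-1252, 3687 and 2946 between strains at 2 weeks, 3553 and 2911 between strains at 4 weeks, and 1125 and 1050 for the interaction. Over the leave-outs of 1 library, the counts higher and lower ranged from 3742 to 4249 and 3263 to 3694 with age in BRFM1218, 2569 to 3283 and 2637 to 3414 with age in 1956-1252, 5401 to 5760 and 4922 to 5245 at 2 weeks, 5476 to 5724 and 5011 to 5188 at 4 weeks, and 2898 to 3284 and 2967 to 3755 for the interaction. Of 64 gene results named by the rule, 62 kept their direction and call in every alternative that tested them; TvLac3 with age in BRFM1218 and TRAVEDRAFT_137860 for the interaction did not. Over all called genes with a symbol and the named identifiers, 3604 of 3757 comparisons with an alternative kept direction and call. Another 143 lost the call with the sign unchanged. In the other 10 the estimate changed sign and the call was also lost. Among genes with a symbol, every alternative kept 26 of 31 calls with age in BRFM1218, 16 of 19 with age in 1956-1252, 23 of 33 between strains at 2 weeks, 21 of 32 at 4 weeks and 24 of 29 for the interaction. The 10 changes of sign were in strain differences of genes with a symbol. None was called in the other direction, at adjusted p of 0.0831 to 0.906 in edgeR. Both settings behind them shift many genes together, and no other cause was tested. With an expression trend removed the log2 difference was -0.02 for LiP10, -0.16 for LiP12, -0.34 for MnP13 and -0.14 for MnP3s at 2 weeks, and -0.35 for LiP4 and -0.06 for MnP5s at 4 weeks. Removal takes out a shift shared by genes of low abundance. Between 1 and 10 CPM the median difference by bin was 0.53 to 1.10 at 2 weeks and 0.58 to 0.90 at 4 weeks. With library size only the log2 difference was 0.18 for VP3at at 2 weeks, and 0.07 for LiP2, 0.14 for MnP8s and 0.05 for TvLac1 at 4 weeks. Leaving out TMM shifts all genes in the same direction. It moved the median difference of all tested genes from 0.09 to 0.60 at 2 weeks and from 0.11 to 0.66 at 4 weeks. All 7 list calls by camera were lost with an estimated correlation and kept in the other 145 comparisons. The settings planned in case the values were normalized were not run, since the files hold counts.

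Libraries with the same replicate number did not deviate together: none of 18 such pairs had a correlation over 0.1 (range -0.21 to 0.10), so the numbers do not pair the samples, and in 15 of 36 comparisons of a library with another group its own number correlated best. With the replicate block, 4085 genes were higher and 3430 lower with age in BRFM1218, 3098 and 2902 with age in 1956-1252, 5592 and 5081 between strains at 2 weeks, 5664 and 5088 at 4 weeks, and 3171 and 3356 for the interaction. Depth limits genes near the floor of up to 0.114 CPM for 3 reads.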

Other observations

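The runs and the correlation of neighbouring genes were chosen after a first look at that correlation. Runs of adjacent genes rose together with age in 1956-1252. The longest, 6 genes from TRAVEDRAFT_156714 to TRAVEDRAFT_75471, rose by log2 fold changes of 1.24 to 3.07, and 4 genes from TRAVEDRAFT_132830 to TRAVEDRAFT_39657 rose by 1.02 to 4.29. In this strain 8 runs of at least 4 adjacent genes were called and at least 2-fold higher, against at most 1 in 100 shuffles of gene order, and 1 run was lower, against at most 0. In BRFM1218 there was 1 run higher, of 5 genes from TRAVEDRAFT_49267 to TRAVEDRAFT_49270 (1.04 to 3.25), and 1 lower, which did not exceed the 4 and 2 runs reached in shuffles.

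The correlation of the age change across 11947 adjacent gene pairs was 0.18 in 1956-1252 and 0.08 in BRFM1218, above the highest of 1000 shuffles in each (0.028 and 0.026). No explanation was tested. The use of strand in the counting was not given in the sources used here.

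The age change depended on model length. In BRFM1218 the median log2 fold change was 0.19 in the 1305 shortest models and -0.30 in the 901 longest, and in 1956-1252 it was 0.11 and -0.08.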
